A study of Arabidopsis thaliana with 12 samples.

How the data were processed

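Chromatin immunoprecipitation sequencing of MAC3A was made in seedlings kept in the dark or in blue light, in 3 replicates per condition, with 3 control samples per condition. Per the submitters' processing notes, Bowtie2, SAMtools, MACS2 2.1.1 and ChIPseeker were used with the genome build TAIR10; their order and parameters are not given in the sources used here. Each of the 6 MAC3A libraries has a peak list in the layout that MACS2 writes, and the deposited lists were used as they are, with no new alignment or peak calling. Which control served which list is not stated, and the control samples' own signal was not analysed here. The labels conflict on points that bear on what was measured. The growth notes name blue light for all samples while the titles name dark and blue. The notes describe MAC3A-GFP lines, while the antibody is given as anti-FLAG. The notes name a GFP-only line as control, while the titles call the controls input. The genotype is given as Columbia-4. The submitters' code for the list of dark replicate 3 carries the replicate mark of dark replicate 2; the lists themselves differ, with 1169 and 1225 peaks and a Jaccard index of 0.528. Groups were taken from the titles.

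As deposited, the fold enrichment of each summit is a ratio that the authors' caller computed over its local background. The authors' lists also give, per summit, the −log10 of the p value and the −log10 of the q value adjusted within each library, with a lowest −log10 q near 2 in every list. The score column, as deposited by the authors, is a whole-number score derived from the q value and was not used. Fold and −log10 q served to describe, rank or filter peaks within a list, since they depend on the depth of each library. Fold was also used with the p value to solve the background of each list, and the enrichment so solved gave 1 scaling between the conditions, a median blue to dark ratio of 0.80 at the regions of all 6 libraries, for the closing section.

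Peaks were distinct intervals on nuclear chromosomes 1 to 5, and all summits of an interval were kept. Peaks of the 6 libraries were merged where they overlapped by at least 1 bp. A region was present in a condition when at least 2 of 3 libraries had a peak there, and specific to a condition when all 3 of its libraries and none of the other condition had one. Summits were placed in gene bodies, within 1 kb of a gene end, or farther away. The gene table gives names and biotypes for assembly TAIR10.1, without strand, exons or untranslated regions. It was used to say which genes lie at peaks, and all coordinates printed are those of the peak lists (TAIR10, counted from 1). As a check of the assemblies against each other, the share of summits in gene bodies was highest with no shift, at 77.8% in the first and 79.7% in the second part of the chromosomes, among shifts of up to 5000 bp either way. The planned share of summits upstream of genes and the planned motif search were not run, since they need strand and sequence; body or 1 kb at either end replaced body or 1 kb upstream after the table was seen.

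Gene lists, tests and alternatives were fixed before the data were examined. They comprised 9 lists with 301 entries, all found in the table, and 5 classes of RNA genes. Each was tested by Fisher's exact test, two-sided, against all other protein-coding genes (27432 in all) for the lists, or all other genes (37887 in all) for the RNA classes. The p values were adjusted by Benjamini-Hochberg over the 28 tests (adjusted over the list alone in this sense), with a threshold of 0.05. As a further test, each list was set against 10000 random lists matched for gene length. Blue and dark libraries were compared by exact permutation tests over the 10 splits of 6 libraries into 3 and 3, where the smallest two-sided p is 0.10. Overlap and gene-body shares were set against 1000 random placements of peaks or positions. Genes were named by a rule: MAC3A; the genes of the 12 regions with the best mean rank by −log10 q in each condition; up to 10 condition-specific regions per condition by median fold; bound members of the light-signalling, HY5 target and elongation lists; and up to 4 bound members of every other list.

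Read totals were not used here. Under the caller's formulas, the fold and p value of a summit fix the expected pileup and the whole number of fragments there. These were solved for 99.8% to 100% of the summits of each list whose p could be inverted, and gave background pileups of 6.13, 5.82 and 6.01 in the dark and 8.82, 9.78 and 9.21 in blue light. The ChIP depth over the control was 1.78 ± 0.131 in the dark and 2.28 ± 0.266 in blue light (SD, n = 3 each). Tested on simulated data, the procedure solved at least 97.0% of the summits of 3 lists and was right for at least 99.9% of these. It assumes that the background is not a multiple of 1/5, and on 3 simulated lists that broke this assumption it found a wrong background, with at most 13.1% of summits solved. On simulated lists of 50 genes bound 5 times as often as others, 99.5% were called and 1.15% of unchanged lists were. The gene lists held from 14 to 71 genes, and smaller lists or weaker differences were not simulated. Simulated regions, 600 shared, 200 specific to blue light and 100 to the dark, were all recovered.

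The alternatives were a −log10 q of at least 5, a fold of at least 3, lists of the 1169 strongest peaks, removal of pericentromeres, rDNA and the mitochondrial insertion, summits within 100 bp or a reciprocal overlap of 50% for sharing, presence in all 3 libraries, and leaving out each library. Chosen after seeing the data were gene bodies only, 3 kb at either end, gene ends only, and blue lists at the dark mean length of 1226 peaks. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.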

Results

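MAC3A is a subunit of the MOS4-associated complex, the plant relative of the Prp19 splicing complex, and carries a U-box ubiquitin ligase domain. It was mapped on chromatin by ChIP-seq in Arabidopsis thaliana seedlings. The series title places MAC3A beside cryptochromes, the blue-light receptors, and HY5, a transcription factor that promotes light-grown development. The question put to the data was therefore where MAC3A lay on the genome, and how its binding in blue light compared with that in darkness. Of the 12 samples, 6 were MAC3A libraries, 3 labelled dark and 3 labelled blue light, each with its own peak list. The other 6 were controls, titled input, 3 per condition, whose own signal was not analysed here. The growth notes name blue light for all samples, so the condition of a library rests on its title. The dark lists held 1285, 1225 and 1169 peaks and the blue lists 1505, 1820 and 1578. Read totals were not used here, and the depth behind each list was estimated from the peak caller's own columns, as given below.

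Most MAC3A peaks lay in genes. In the dark, 82.0 ± 1.28% of summits (SD, n = 3) fell inside a gene body and 16.4 ± 1.22% within 1 kb of a gene end. In blue light the shares were 76.5 ± 0.469% and 21.7 ± 0.494% (SD, n = 3). Random positions on the same chromosomes fell inside gene bodies in 64.1% of cases for the dark lists and 64.2% for the blue lists. None of 1000 draws reached the observed share in either condition (permutation test, two-sided, p = 0.001, the smallest value these draws can give). These draws pooled the summits of a condition's 3 libraries, which share many regions, and covered whole chromosomes. As a more local measure, the summits of all lists shifted by 5000 bp fell inside gene bodies in 64.7% to 69.9% of cases. Unshifted they did so in 77.8% and 79.7% of cases, for the first and second part of the chromosomes. Summits more than 1 kb from any gene made up 1.55 ± 0.0578% in the dark and 1.77 ± 0.0332% in blue light (SD, n = 3), against 11.1% and 11.0% of the random positions. Random positions lay within 1 kb of a gene end in 24.8% of cases for both sets of lists, more than the summits did in either condition (permutation test, two-sided, p = 0.001, the smallest value these draws can give). The share inside gene bodies was lower in each blue library than in each dark library (exact permutation test, two-sided, p = 0.10, n = 3 per condition). The difference of -5.48 points was -3.62 with lists of equal length and -1.42 among peaks with a fold of at least 3. With 3 libraries against 3, 0.10 is the smallest p that this test can reach, here and below. It measures only the spread between these libraries, since nothing in the labels says that they came from separate cultures.

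The strongest MAC3A regions were largely shared between darkness and blue light. Of the 12 regions with the best mean rank by the authors' −log10 q in each condition, 10 were in both sets. The last dark place was tied between 3 regions, and either other choice would add a shared region. The best mean rank in both conditions belonged to a region on chromosome 1 from 29833578 to 29835312 (TAIR10), over the tRNA gene AT1G79300 and the metacaspase gene MC7 (AT1G79310). Its fold enrichment was 20.5 to 25.0 in the dark lists and 13.7 to 17.3 in the blue lists. Each fold is the peak's own value by the authors' caller and depends on the depth of its list. Regions over the receptor kinase genes AT1G05700 (chromosome 1, 1709842 to 1711378) and AT5G59680 (chromosome 5, 24046619 to 24048237) were in both sets. So were regions over the cellulose synthase-like gene CSLA14 (AT3G56000), TBL33 (AT2G40320), the beta-glucosidase gene BGLU16 (AT3G60130) and the heat shock factor gene HSFA7A (AT3G51910). The remaining shared regions lay over AT1G10220, the auxin biosynthesis gene YUC3 (AT1G04610) and AGL81 (AT5G39750), with the ribosomal protein gene RPL5B (AT5G39740) within 1 kb of the last. Regions over AT1G70550 and AT2G42450 completed the dark set, the last of them in a tie. Regions over AT4G37230 with AT4G37235 and over AT5G59050 completed the blue set. Both had the same mean dark rank as the region over AT2G42450, 12, and the tie went to the first in chromosome order. The gene of MAC3A itself (AT1G04510) had a summit in 1 of the 6 libraries, blue replicate 2, in a peak on chromosome 1 from 1227825 to 1228065 with a fold of 3.18.

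A core of regions was found in both conditions. Merging overlapping peaks of the 6 libraries gave 2917 regions, of which 1118 were present in at least 2 dark libraries and 1478 in at least 2 blue libraries. The 808 regions that met both criteria made up 72.3% of the dark and 54.7% of the blue set. Random placement of the same peaks gave 0.063 such regions on average and at most 2 (permutation test with 1000 placements, one-sided, p = 0.001, the smallest value these placements can give). The peaks of each library were moved independently, which also breaks the agreement between replicates. The p value therefore covers that agreement too and does not measure sharing between the conditions alone. All 6 libraries shared 533 regions, and 1002 regions came from a single library. Peaks of libraries from the same condition overlapped more than peaks across conditions. The mean Jaccard index in base pairs was 0.525 ± 0.00776 (SD, 3 pairs) within the dark, 0.517 ± 0.00534 (SD, 3 pairs) within blue light and 0.364 ± 0.00986 (SD, 9 pairs) between the conditions. The difference of 0.157 was the highest among the 10 splits of the libraries into 3 and 3, the next being -0.0135 (exact permutation test, p = 0.10, n = 3 per condition, one-sided for a higher overlap within conditions).

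**Figure D1:**
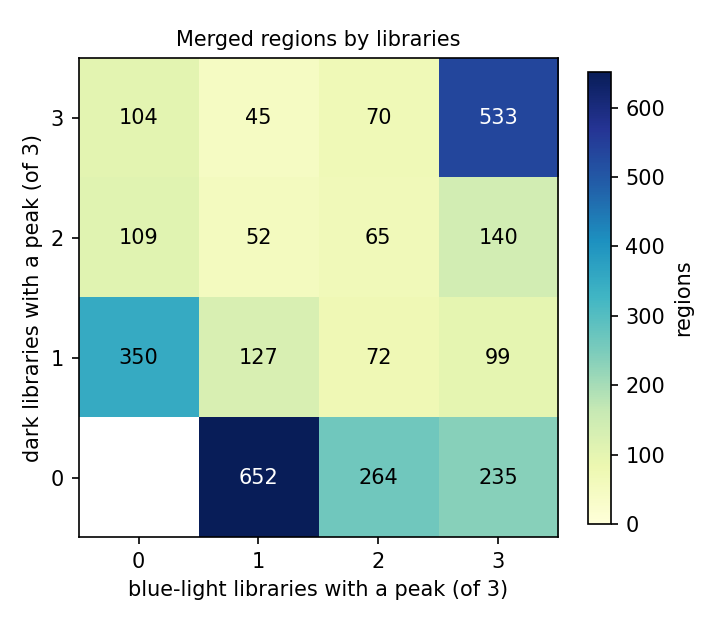
Number of merged regions by the number of dark libraries (vertical axis, 0 to 3) and blue-light libraries (horizontal axis, 0 to 3) with a peak there. All 6 libraries share 533 regions, 235 regions are in all blue and no dark libraries, and 104 are in all dark and no blue libraries.

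Blue-light lists held more peaks than dark lists, with a mean of 1634 ± 165 against 1226 ± 58.0 (SD, n = 3 each), a ratio of 1.33 (exact permutation test, two-sided, p = 0.10). The covered length was 716 ± 68.9 kb in blue light and 538 ± 23.1 kb in the dark (SD, n = 3 each), at a mean peak width of 438 bp in both. At a −log10 q of at least 5 the ratios of peak number and covered length were 1.1 and 1.16, and at a fold of at least 3 they were 0.793 and 0.940. Folds were lower in the blue lists, with a median of 2.81 against 3.35, so the fold limit removed more blue peaks. The fold and p columns also gave the background behind each list under the formulas of the authors' caller. The blue libraries carried 21.1 ± 1.39 fragments per background position and the dark libraries 10.6 ± 0.606 (SD, n = 3 each), a ratio of 1.99 (exact permutation test, two-sided, p = 0.10). This quantity is depth times fragment length, and the blue lists were therefore called at a higher background coverage.

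Regions seen in all 3 blue libraries and no dark library numbered 235. Of the 10 with the highest median fold, 3 lay over tRNA genes. These were AT5G23665 (chromosome 5, 7981220 to 7981574, fold 4.03), AT1G07100 with F2KP (AT1G07110; chromosome 1, 2177521 to 2178192, fold 4.01), and AT5G65015 with the asparagine synthetase gene ASN2 (AT5G65010; chromosome 5, 25972471 to 25972872, fold 3.98). Another covered the beta-galactosidase gene BGAL4 (AT5G56870) with AT5G56880 (chromosome 5, 23004110 to 23009001, fold 3.69). AT2G32150 lay in a region on chromosome 2 from 13658925 to 13661314 (fold 3.66). DIN4 (AT3G13450), a gene of branched-chain amino acid breakdown named for its induction in darkness, shared a region with the m6A reader gene ECT2 (AT3G13460; chromosome 3, 4384348 to 4384947, fold 3.56). The other regions lay over AT5G20700, PATL1 (AT1G72150), AT1G35513, and VDAC1 (AT3G01280) with HIR2 (AT3G01290). Without blue replicate 1 the count was 360. It was 108 with lists of equal length, 59 at a −log10 q of at least 5 and 48 at a fold of at least 3, where regions of all dark and no blue libraries numbered 119, 58 and 80, so the excess over the dark did not hold there. Poisson estimates of how many blue regions the depth of the dark libraries would miss ran from 49.9 to 226 with the enrichment assumed and with a correction chosen after the first values were seen.

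Regions seen in all 3 dark libraries and no blue library numbered 104. The highest median fold, 6.73, belonged to ERD5 (AT3G30775), a proline dehydrogenase gene (chromosome 3, 12450342 to 12451069). AT1G80810 carried 2 such regions on chromosome 1, from 30368409 to 30368894 with a fold of 5.95 and from 30366332 to 30367283 with a fold of 5.30. The plastid fibrillin gene FIB4 (AT3G23400) had a region on chromosome 3 from 8377529 to 8378260 (fold 5.56). The photosystem I subunit gene PSAF (AT1G31330) had one on chromosome 1 from 11215171 to 11215940 (fold 4.31). The remaining regions lay over AT1G07135, AT4G06597, PHO1;H1 (AT1G68740), a member of a phosphate transporter family, and AT3G10300, and on chromosome 2 from 17220195 to 17220755 with no gene within 1 kb (fold 4.03). The 339 regions specific to either condition compared with at most 18 in any other split of the libraries into 3 and 3.

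Several light-signalling genes had MAC3A peaks, some in libraries of both conditions and some in those of 1 condition. A gene was counted as bound in a condition when a summit lay in its body or within 1 kb of either end in at least 2 of the 3 libraries. This held for 1731 of 37887 genes in the dark (1539 of them protein-coding), for 2345 in blue light (2018 protein-coding) and for 1280 in both. With gene bodies alone, 934 and 1130 genes were bound. Of 39 photoreceptor and light-signalling genes, 8 were bound in blue light, against 7.34% of other protein-coding genes (odds ratio 3.26, Fisher's exact test, two-sided, adjusted p = 0.0207). In the dark 4 were bound, against 5.6% of the others (odds ratio 1.93, Fisher's exact test, adjusted p = 0.459). HFR1 (AT1G02340), a negative regulator of shade growth, and BBX21 (AT1G75540), a B-box activator of HY5, had a summit in all 3 blue libraries and in no dark library, with median folds of 2.59 and 3.01. PIF5 (AT3G59060), BBX22 (AT1G78600) and the UV-B feedback gene RUP2 (AT5G23730) had one in all 3 blue and 1 dark library. PIF4 (AT2G43010) had summits in 2 blue and 1 dark library, and GBF1 (AT4G36730) in 2 blue libraries only. The cryptochrome gene CRY1 (AT4G08920) was the reverse. Peaks between 5724279 and 5726465 on chromosome 4 had summits in its body in all 3 dark libraries (median fold 3.78) and in no blue library. HY5 (AT5G11260) and PIF3 (AT1G09530) had summits in 2 dark and 1 blue library, and BBX28 (AT4G27310) had one beside the gene in all 6. At a fold of at least 3 the direction for HY5 turned, to 1 more blue than dark library, and HFR1 had no summit left in excess. CRY1 kept its 3 dark and no blue libraries at that fold, at a −log10 q of at least 5 and with lists of equal length. BBX21 had no summit inside its body. The blue-light call passed in 9 of 16 alternatives (Fisher's exact test or matched lists, adjusted p from 0.000523 to 0.390). Of these 9, the 3 that left out a dark library could not change it. It ended with lists of equal length (Fisher's exact test, adjusted p = 0.0567) and without blue replicate 3 (Fisher's exact test, adjusted p = 0.0668). It also ended on random lists matched for gene length (permutation test, adjusted p = 0.0644), at a −log10 q of at least 5, at a fold of at least 3 and with gene bodies only. With 3 kb at either end the dark list passed (odds ratio 2.86, Fisher's exact test, adjusted p = 0.0337, the lowest of a range up to 0.941). Per library, 9.33 ± 1.53 members had a summit in blue light and 5 in each dark library (SD, n = 3 each, exact permutation test, two-sided, p = 0.10).

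Known HY5 target genes did not pass the test in either condition under the main rule. In blue light 6 of 40 were bound, against 7.35% of other protein-coding genes (odds ratio 2.23, Fisher's exact test, two-sided, adjusted p = 0.164), and in the dark 3 of 40 (odds ratio 1.36, Fisher's exact test, adjusted p = 0.624). LDOX (AT4G22880), an anthocyanin biosynthesis gene, and GA2OX2 (AT1G30040), which inactivates gibberellins, had summits in their bodies in all 6 libraries. The LDOX peaks lay on chromosome 4 between 12005524 and 12006464 and had median folds of 12.3 in the dark and 9.13 in the blue lists. The clock gene CCA1 (AT2G46830) had a summit in all 3 blue libraries and no dark library, and the auxin repressor gene IAA7 (AT3G23050) in 2 blue libraries, differences that were both 0 at a fold of at least 3. The other bound members, RUP2, BBX22 and HY5, were among the light-signalling genes above. With gene bodies only, a setting added after the data were seen, the blue-light list passed (odds ratio 3.73, Fisher's exact test, adjusted p = 0.0362). Over the 16 alternatives the adjusted p ran from 0.0362 to 0.965, and none of the other 15 passed.

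Genes of hypocotyl elongation and growth hormones were bound in 7 of 71 cases in each condition (odds ratios 1.84 in the dark and 1.38 in blue light, Fisher's exact test, two-sided, adjusted p = 0.257 and 0.567). The expansin genes EXPA1 (AT1G69530) and EXPA10 (AT1G26770), the proton pump gene AHA2 (AT4G30190) and the gibberellin biosynthesis gene GA20OX2 (AT5G51810) had summits in all 6 libraries. The cell wall genes XTH18 (AT4G30280) and TCH4 (AT5G57560) had them in 3 dark and no blue libraries, but for XTH18 the difference was 0 at a −log10 q of at least 5 and at a fold of at least 3. The shade-induced gene ATHB2 (AT4G16780) had them in 3 blue and no dark libraries, PIL2 (AT3G62090) in 3 blue and 2 dark, and the DELLA gene GAI (AT1G14920) in 2 blue libraries. With lists of equal length ATHB2 was left with a difference of 1 library. With gene bodies only, the dark list passed (odds ratio 2.87, Fisher's exact test, adjusted p = 0.0477, the lowest of a range up to 0.647 over the alternatives).

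**Figure D2:**
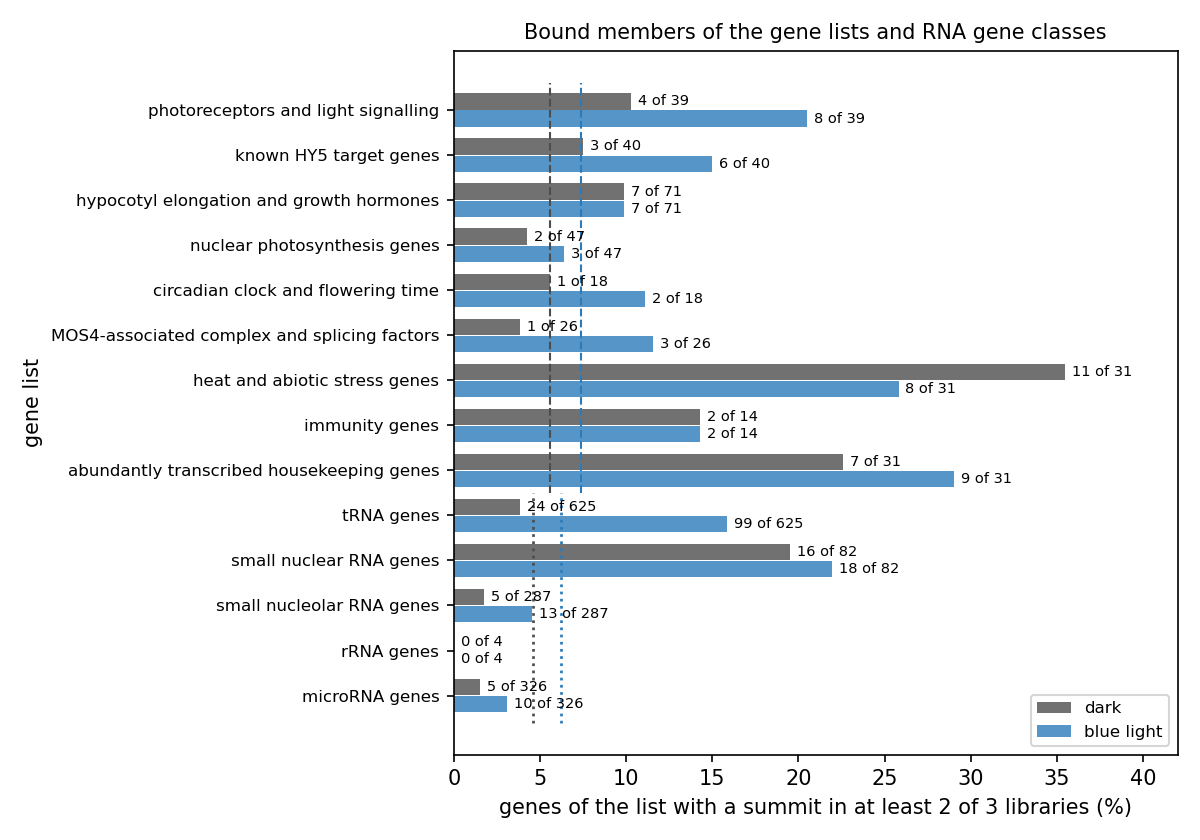
Percent of the members of each gene list and RNA gene class with a summit in at least 2 of 3 libraries (horizontal axis), in the dark (grey) and in blue light (blue), with the number of bound members beside each bar. Dashed lines give the share among protein-coding genes outside a list and dotted lines that among genes outside an RNA class (medians over the lists or classes); tRNA genes are bound in 24 of 625 cases in the dark and 99 of 625 in blue light, and stress genes in 11 of 31 cases in the dark.

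Heat and abiotic stress genes were bound more often than other genes in both conditions. In the dark 11 of 31 were bound (odds ratio 9.31, Fisher's exact test, two-sided, adjusted p = 6.98e-06) and in blue light 8 of 31 (odds ratio 4.39, Fisher's exact test, adjusted p = 0.00577), 7 of them in both. The small heat shock protein gene HSP17.4 (AT3G46230) and the zinc finger gene ZAT12 (AT5G59820) had summits in their bodies in all 6 libraries. So did the dehydration marker RD29A (AT5G52310) and NCED3 (AT3G14440), the key gene of stress-induced abscisic acid synthesis. Chosen after their values were seen, the cold regulators CBF2 (AT4G25470) and CBF3 (AT4G25480) and WRKY40 (AT1G80840) had summits in all 3 dark and no blue libraries. DREB2A (AT5G05410) had them in all 3 blue and no dark libraries. CBF1 (AT4G25490) had summits in all 6 libraries, in its body in 3 dark and 1 blue. At a −log10 q of at least 5 the difference was 2 libraries for CBF2 and CBF3 and 1 for DREB2A. By their gene numbers the 3 CBF genes lie close together, and Fisher's exact test counts such neighbours as independent. The blue-light call ended among peaks with a fold of at least 3 (Fisher's exact test, adjusted p = 0.0688, range 0.000632 to 0.0719 over the alternatives).

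Abundantly transcribed housekeeping genes were also bound more often than other genes, 7 of 31 in the dark (odds ratio 4.93, Fisher's exact test, two-sided, adjusted p = 0.00577) and 9 of 31 in blue light (odds ratio 5.17, adjusted p = 0.00158). ACT8 (AT1G49240) and SAM1 (AT1G02500) had summits in all 6 libraries, EF1A4 (AT5G60390) in 3 blue and no dark libraries, and ACT7 (AT5G09810) in 3 dark and 2 blue. The difference for EF1A4 was 0 with lists of equal length, at a −log10 q of at least 5 and at a fold of at least 3. For ACT7 it turned with gene bodies only. Both calls ended at a −log10 q of at least 5, where the odds ratios were 3.40 in the dark and 0.893 in blue light. The blue one also ended without blue replicate 3 (Fisher's exact test, adjusted p = 0.0800, range 0.00117 to 1 over the alternatives).

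The other lists held few bound genes. Nuclear photosynthesis genes gave 2 of 47 in the dark and 3 of 47 in blue light. Among them PSAF had summits in 3 dark and no blue libraries, PSBR (AT1G79040) in 3 blue and no dark, PSAN (AT5G64040) in 3 blue and 2 dark, and LHCB4.1 (AT5G01530) in 2 blue. Clock and flowering-time genes gave 1 and 2 of 18, with CCA1 as above, LUX (AT3G46640) in 2 dark libraries and GI (AT1G22770) in 2 blue and 1 dark. Genes of the MOS4-associated complex and of splicing factors gave 1 and 3 of 26. These were SR30 (AT1G09140) in 3 dark and 2 blue libraries, RS40 (AT4G25500) in 2 blue and 1 dark, and GRP8 (AT4G39260) in 2 blue. Immunity genes gave 2 of 14 in both conditions, namely FRK1 (AT2G19190), with median folds of 10.9 in the dark and 6.63 in the blue lists, and EDS1 (AT3G48090). The direction turned for GI at a fold of at least 3 and for SR30 at a −log10 q of at least 5, and PSBR was left with a difference of 1 library with lists of equal length. None of these 4 lists passed Fisher's exact test in either condition after adjustment over the 28 tests, and none had an unadjusted p under 0.05.

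Among RNA genes, tRNA genes set the blue-light libraries apart. A summit lay at 102 ± 8.39 tRNA genes per blue library and 29.0 ± 2.00 per dark library (SD, n = 3 each), a ratio of 3.51 (exact permutation test, two-sided, p = 0.10). In blue light 99 of 625 tRNA genes were bound (odds ratio 2.93, Fisher's exact test, two-sided, adjusted p = 2.91e-16). Their summits lay in 96 separate regions, a count that includes regions of a single blue library. In the dark 24 of 625 were bound (odds ratio 0.832, Fisher's exact test, adjusted p = 0.586). Random lists matched for gene length turned that direction, with 16.3 bound in the dark on average (permutation test, adjusted p = 0.151). With summits inside the short tRNA gene itself, 30 were bound in blue light and 2 in the dark, and the ratio per library was 6.05. All 3 blue libraries and no dark library had a summit at 33 tRNA genes, against 2 for the reverse.

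Small nuclear RNA genes, which encode the RNAs of the spliceosome among others, were bound in both conditions. In the dark 16 of 82 were bound (odds ratio 5.10, Fisher's exact test, two-sided, adjusted p = 7.52e-06) and in blue light 18 of 82 (odds ratio 4.29, adjusted p = 1.51e-05), 16 of them in both and 14 in all 6 libraries. MicroRNA genes were bound less often than other genes, 5 of 326 in the dark and 10 of 326 in blue light (odds ratios 0.323 and 0.477, Fisher's exact test, two-sided, adjusted p = 0.0167 and 0.0392). Small nucleolar RNA genes were bound less often in the dark, 5 of 287 (odds ratio 0.369, Fisher's exact test, adjusted p = 0.0392), and 13 of 287 were bound in blue light (Fisher's exact test, adjusted p = 0.459, but 0.0395 without blue replicate 2 and 0.0268 without blue replicate 3), where matched lists gave 16.6 (permutation test, adjusted p = 0.693). None of the 3 lower shares that passed Fisher's exact test also passed against random lists matched for gene length (permutation test, adjusted p = 0.424, 0.122 and 0.595), and the small nucleolar RNA call also ended without any single dark replicate (Fisher's exact test, adjusted p = 0.160, 0.12 and 0.250 without replicates 1, 2 and 3). The microRNA call in the dark ended without dark replicate 2 (Fisher's exact test, adjusted p = 0.0615). None of the 4 rRNA genes of the table was bound.

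**Figure D3:**
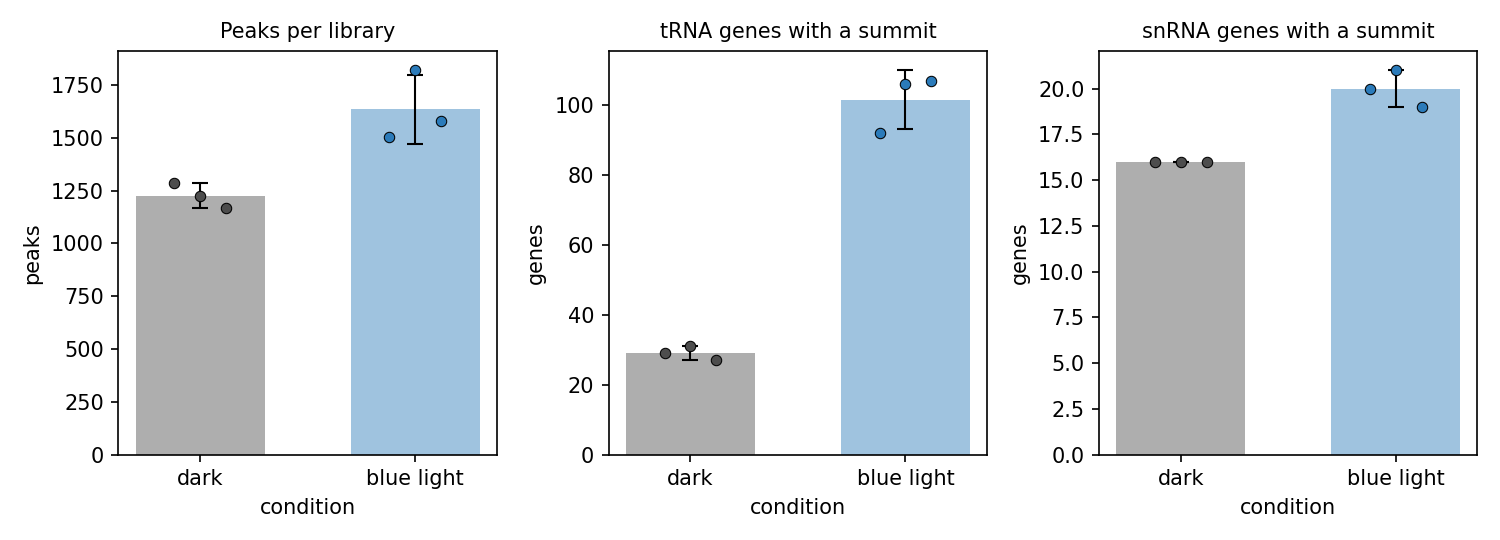
Peaks, tRNA genes with a summit and snRNA genes with a summit per library (vertical axes, counts) in the dark and in blue light. Bars are means, error bars SD and points the 3 libraries of each condition; tRNA genes average 29.0 in the dark and 102 in blue light, and peaks 1226 and 1634.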

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

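The settings gene bodies only, 3 kb at either end, gene ends only and blue lists at the dark mean length were chosen after the data were seen, and the other alternatives before. The calls for stress genes in the dark, tRNA genes in blue light and snRNA genes in both conditions stayed past the threshold under all 16 alternatives run. For a list or gene count of 1 condition, the 3 settings that leave out a library of the other condition cannot change its value. Shortened blue lists cannot change a value in the dark either. Such settings are no support, though they enter the counts and ranges given here. Over the results that answer a comparison, 254 values stayed, 36 moved, 34 lost a call and 3 reversed, and the cause was not tested in any of these cases. Ratios and differences stayed when they kept their direction and moved by less than their spread. Counts of regions, genes and list calls stayed when they changed by at most 1.5 times. List calls stayed when they kept their direction and side of the threshold. At a −log10 q of at least 5, the peak ratio was 1.1, the covered-length ratio 1.16, the overlap difference 0.131, and there were 439 shared, 59 blue-specific and 58 dark-specific regions, 950 genes bound in the dark, 1151 in blue light and 7 list calls. Calls were lost there for light signalling in blue light (odds ratio 3.07), housekeeping in the dark (3.40) and snoRNA in the dark (0.548), and housekeeping in blue light reversed to an odds ratio of 0.893. At a fold of at least 3, the peak ratio reversed to 0.793 and the covered-length ratio to 0.940. The overlap difference was then 0.113, with 465 shared, 48 blue-specific and 80 dark-specific regions and 1038 genes bound in blue light against 1216 in the dark, so that the dark exceeded blue light in both, a gene-body difference of -1.42 points, 6 list calls and a tRNA ratio of 2.36. Calls were lost for light signalling (2.49), stress (4.44) and housekeeping (2.06) in blue light, and housekeeping (3.61) and snoRNA (0.533) in the dark. With equal list lengths, the covered-length ratio was 1.1, the overlap difference 0.142, blue-specific regions 108 against 119 dark-specific ones, the gene-body difference -3.62 points and the tRNA ratio 3, and calls were lost for light signalling (3.16) and housekeeping (3.34) in blue light and snoRNA in the dark (0.386). With blue lists at the dark mean length the values were 1.1, 0.142, 113 (against 124 dark-specific), -3.80 points and 2.98, with calls lost for light signalling (3.01) and housekeeping (3.18) in blue light. Without pericentromeres, rDNA and the mitochondrial insertion, snoRNA in the dark lost its call (0.390). With summits within 100 bp the overlap difference was 0.124. With all 3 of 3 libraries required there were 533 shared regions and 1132 genes bound in the dark, and calls were lost for housekeeping in blue light (3.6) and for snoRNA (0.457) and microRNA (0.300) in the dark. With gene bodies only, 934 and 1130 genes were bound in the dark and in blue light, the tRNA ratio was 6.05, and light signalling in blue light lost its call (2.98). With 3 kb at either end, 3069 and 3918 genes were bound, the tRNA ratio was 2.46, and calls were lost for stress in blue light (2.57), housekeeping in the dark (2.78), snoRNA in the dark (0.988) and microRNA in blue light (0.718). With gene ends only, snoRNA in the dark (0.380) and microRNA in blue light (0.489) lost their calls. Against lists matched for gene length, where the value is the ratio to the matched mean, calls were lost for light signalling in blue light (2.68), snoRNA in the dark (0.603), and microRNA in the dark (0.551) and in blue light (0.549). Leaving out each library in turn gave peak ratios of 1.26 to 1.39, covered-length ratios of 1.26 to 1.39, overlap differences of 0.152 to 0.163, 655 to 726 shared regions, 263 to 360 blue-specific regions (360 without blue replicate 1), 112 to 147 dark-specific regions, 1295 to 1731 genes bound in the dark, 1751 to 2345 in blue light, gene-body differences of -6.00 to -4.76 points, 9 to 12 list calls and tRNA ratios of 3.39 to 3.67. The odds ratios were 2.89 to 4.02 for light signalling in blue light, 8.91 to 12.2 and 4.39 to 5.96 for stress in the dark and in blue light, 4.37 to 5.28 and 3.05 to 5.17 for housekeeping, 2.49 to 2.93 for tRNA in blue light, 5.10 to 6.39 and 4.29 to 5.85 for snRNA, 0.369 to 0.473 for snoRNA in the dark, and 0.261 to 0.338 and 0.255 to 0.477 for microRNA. With replicate numbers as blocks the peak ratio was 1.33, the tRNA ratio 3.50 and the gene-body difference -5.48 points. Residuals of libraries with the same number did not go together (r = -0.0025, 0.0050 and 0.00067). The lists thus gave no sign of pairing by number, but this check cannot exclude that such libraries were handled together. For named genes and regions and for lists without a call, 1313 values stayed, 168 moved and 8, all of them list tests, passed the threshold. With gene bodies only these were HY5 targets in blue light (3.73), elongation (2.87), tRNA (0.125) and starvation genes (4.23) in the dark, and snoRNA in blue light (0); the short RNA genes leave little room for a summit in their bodies, and against length-matched lists tRNA in the dark had a ratio of 1.47. The others were light signalling in the dark with 3 kb at either end (2.86) and snoRNA in blue light without blue replicate 2 (0.364) and without blue replicate 3 (0.340). The upstream share and the motif search were not run for lack of strand and sequence, nor were their alternatives. Read depth was known only through the background coverage, which limits what an absent weak peak in the dark lists can say.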

Other observations

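The tests of genes induced by darkness and sugar starvation, of gene families, of snRNA against tRNA genes, the corrections of the depth estimates, and the comparison of repeat windows with shared regions were chosen only after the results that prompted them were seen.

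Genes that darkness and sugar starvation induce were often bound in the blue-light libraries. The list was prompted by DIN4, BGAL4 and AT2G32150 among the blue-specific regions, and these and ERD5 were left out of the test. Of the 25 other members, 13 (52%) were bound in blue light, against 7.31% of other protein-coding genes (odds ratio 13.7, Fisher's exact test, two-sided, p = 3.93e-09). In the dark 3 were bound (odds ratio 2.3, Fisher's exact test, p = 0.163), and with gene bodies only the dark list passed too (odds ratio 4.23, Fisher's exact test, p = 0.0422, range 0.0422 to 1 over 15 alternatives). BCE2, DIN10, TPS8, AT5G22920 and AKINBETA1 had a summit in all 3 blue and no dark libraries, and ASN1, DIN9 and GDH2 had one in all 6. The list had 10 genes bound in blue light alone and 0 in the dark alone, against 866 and 399 other genes (Fisher's exact test, two-sided, p = 0.0363). Of the genes left out of these counts, ERD5 had a summit in all 3 dark and no blue libraries. DIN4, BGAL4 and AT2G32150 were the reverse. Per library, 12 ± 2 members had a summit in blue light and 3.33 ± 0.577 in the dark (SD, n = 3 each, exact permutation test, two-sided, p = 0.10, the smallest possible). The blue odds ratio ranged from 4.1 to 17.5 over 15 alternatives (Fisher's exact test, p from 2.40e-09 to 0.0456), of which the 3 that left out a dark library could not change it. Expression was not measured here, a swap of the labels could not be tested, and the depth stays open for the difference between the conditions.

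Among 90 families of at least 15 genes with a shared symbol, 2 were bound more often than other genes (180 tests of Fisher's exact test, two-sided). The family tests were run under the main rule only, with none of the alternatives. Cysteine-rich receptor-like kinases (CRK) were bound in 10 of 40 cases in the dark (odds ratio 5.64, Fisher's exact test, adjusted p = 0.00973) and 6 in blue light. The 10 lay at 9 separate regions and the 6 at 5, counts that include regions of a single library. By their gene numbers, CRK10, CRK12, CRK13, CRK19 and CRK20 lie close together on chromosome 4, and CRK2 and CRK3 on chromosome 1. Fisher's exact test counts such neighbours as independent. CRK12, CRK13, CRK20, CRK40 and CRK41 had summits in all 6 libraries, while CRK10 and CRK26 had them in 3 dark and no blue libraries. CIPK genes, kinases of calcium signalling, were bound in 7 of 21 cases in blue light (odds ratio 6.32, Fisher's exact test, adjusted p = 0.0481) and 4 in the dark. CIPK15, CIPK19, CIPK21 and CIPK22 had summits in all 6 libraries and CIPK1 in 3 blue and no dark libraries. The difference between conditions was not tested for either family, and all these members were chosen after their values were seen.

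Condition-specific regions went both ways, 235 for blue light and 104 for the dark, but 108 and 119 with lists of equal length and 48 and 80 at a fold of at least 3. A Poisson model of the depth put 49.9 (SD 6.20) blue regions out of reach of the dark libraries at the median of each region's 3 enrichments and 161 at the lowest; on simulated data, where 130 were missed, these picks gave 117 and 260. Within a condition, however, misses exceeded the model by up to 3.34 and 1.4 times, and multiplying by these, a correction added after the first values were seen, gave 166 (SD 20.7) and 226 (SD 13.7); between these estimates the depth and a change of binding cannot be told apart for the blue-specific regions. The lowest pick, corrected, gave 1.11 missed regions for the 104 dark-specific ones, and 68.1 (SD 7.30) with enrichment in the blue libraries scaled by 0.80. On simulated data the picks gave 0.00832 and 0.0672 where 2 dark regions were missed, so the model ran low in this direction. The 0.80 came from regions called in all 6 libraries, which kept enough enrichment in blue light to be called, so 68.1 may be too low. Depth at equal enrichment fell far short of the 104. A generally lower enrichment in the blue libraries cannot be told apart from a loss of binding in blue light, which stays a hypothesis. Only 1 of the 10 splits, the real one, gave 339 regions, with at most 18 in any other, but 10 splits are too few for a share under 0.05.

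The tRNA genes were bound mainly in the libraries labelled blue. With lists of equal length the blue to dark ratio was still 3, which argues against longer lists as the cause, and the depth model, corrected in the same way, put 13.8 (SD 3.50) of the 33 tRNA genes seen in all blue and no dark libraries out of reach. The log ratio of snRNA genes was 0.178 of that of tRNA genes, while snoRNA (0.480) and microRNA genes (0.417) lay between. The snoRNA counts were 7.67 ± 2.52 in the dark and 14 ± 7 in blue light (SD, exact permutation test, two-sided, p = 0.3). The microRNA counts were 5.33 ± 1.53 and 9 ± 2 (SD, exact permutation test, two-sided, p = 0.2), so neither gain was clear. The log ratios count genes with a summit and argue only against an equal gain in the number of called genes. In each dark library 16 snRNA genes already had a summit, and more signal at these could not raise the count. A gain of signal at all small structured RNA genes therefore stays open. Unspecific recovery that the control shows too cannot be told apart from binding. The expected pileup near tRNA genes was at most 1 times that at other summits in the 3 blue libraries. However, only called summits were seen, and most of those near tRNA genes in blue replicates 2 and 3 lay at the floor of that measure. The controls are titled input, and an input would not show unspecific recovery in the immunoprecipitation. A higher occupancy of tRNA genes in blue light may be 1 explanation among these, and a difference in chromatin preparation was not tested.

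Strong regions shared by all 6 libraries might come from the line or the mapping rather than from MAC3A. Of the 100 strongest, 15% had another within 50 kb, inside the 4% to 20% of random draws of shared regions. The strongest were thus not clearly more clustered than other shared regions. Since the draws came from these same shared regions, amplified or inserted segments behind shared regions in general cannot be excluded. Pericentromere, rDNA and mitochondrial insertion windows held 8% of them, against 6.19% of all regions shared by the 6 libraries and 2% to 11% in random draws of these. The share of the genome in these windows, 26.4%, is no fair measure for peaks that lie mostly in genes, so repeats and mapping stay open. No biological explanation was tested for these regions, and open chromatin stays open too.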
